A study of Homo sapiens with 3 samples.

How the data were processed

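Polyadenylated RNA was sequenced from human bone marrow stromal cells, primary cells that can form bone, cartilage and fat in culture, grown on discs of silicon nitride (SiN), A-Ti or M-Ti. A-Ti and M-Ti are 2 kinds of titanium disc whose abbreviations the labels do not expand. Per the labels' protocols, cells were seeded at 40000 per well, received osteogenic medium from confluence on, and were harvested at day 21. RNA of 3 wells was combined in equal amounts per disc type before library preparation, so that each disc type is represented by 1 library. Libraries were made with a stranded mRNA kit that marks the second cDNA strand with dUTP, per the labels' protocols. The 3 wells of a pool cannot be separated, and no spread between cultures could be estimated.

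The authors deposited 1 table of estimated counts (expected counts, with whole and fractional values) for 19293 genes. Partek is named as the software per the submitters' processing notes; its version, the aligner, the annotation release and the use of strand in counting are not given in the sources used here. The submitters' processing notes name the mouse build GRCm38, whereas the deposited table holds human Ensembl gene identifiers. Of these, 96.2% were found in GENCODE release 29 for GRCh38; 100.0% of the matched genes were on the same chromosome and 64.1% had the same start. Coordinates below are therefore GRCh38 positions as deposited, with the end given as the deposited stop minus 1, the form in which 64.4% of ends equalled that annotation. The smallest sum over the 3 libraries was 10 counts, so genes below that sum are not analysed here. Estimated counts are divided among overlapping and near-identical genes by the counting software. Values of read-through genes, pseudogenes, close paralogs and antisense genes are uncertain for that reason.

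Estimated counts were rounded to whole numbers. Libraries were scaled with the TMM method of edgeR 4.0.16 in R 4.3.3 and expressed as CPM, counts relative to the scaled library total in the usual unit. The scaling factors were 1.0121 for SiN, 1.0086 for A-Ti and 0.9796 for M-Ti. The 46 genes on chromosome Y or named XIST entered the library totals and nothing else. Genes with at least 1 CPM in at least 1 library were compared, which left 13639. Log2 folds were taken after adding 0.5 counts. The 95% interval of each ratio of counts came from the exact conditional binomial distribution (Clopper-Pearson). These intervals cover counting error only: reads are not independent molecules, and the differences between libraries have no replicate check. No p-value was computed. A gene was called higher or lower when its fold was at least 2 and its interval excluded equal levels. A second threshold of 1.5-fold was chosen after the data were examined, because few genes passed the first. Statements that a gene differed beyond counting error refer to the interval alone.

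Lists of genes (42 lists, 1100 entries) were fixed before the data were examined, and 4 of them answer the question in the title of the series: nuclear-encoded and mitochondrially encoded subunits of oxidative phosphorylation (OXPHOS), angiogenic secreted factors and osteoblast differentiation markers. The median log2 fold of each list with at least 5 compared genes was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list was said to stand apart below percentile 2.5 or above percentile 97.5. These percentiles describe the libraries and not the discs. Named genes had a symbol and at least 5 CPM in at least 1 library. They were the 12 highest and 12 lowest in SiN among genes past the 2-fold rule against both titanium libraries, the 6 highest and 6 lowest of each single comparison, the 6 highest and 6 lowest of A-Ti and of M-Ti against both others, the 4 most abundant members and the 4 with the largest mean difference of SiN from titanium in each of the 4 main lists, and up to 4 members of every other list by that difference. The rule was fixed before the data were examined; the text leaves some of these genes out for length, 1 is not reported here, and the text says where a gene was chosen after its values were seen.

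Transcript GC content, the median over the transcripts of a gene in GENCODE 29, was available for 13413 of the compared genes (98.3%). As an alternative added after the data were examined, a lowess trend of the log2 fold on GC content was taken out (span 0.3, 3 iterations; statsmodels 0.14.6), alone or followed by a trend on transcript length. The other added alternative was a count over named protein-coding genes without read-through genes. Alternatives set beforehand were scaling by total counts, by DESeq2 1.42.0 size factors or by TMM on nuclear-encoded genes, no filter or a filter at 5 CPM, 5 added counts, thinning of all libraries to the shallowest total of 48766246 counts, the fold without the counting interval, list means, and unmatched random lists. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

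The rules were tested on simulated data. Counts were drawn from the means and library sizes of the real libraries, with 200 genes changed in SiN against both others, and 13484 genes passed the filter. The 2-fold rule recovered 12 of 50 genes simulated at 2-fold, 50 of 50 at 3-fold and 49 of 50 at 4-fold, and called 0 of 13285 unchanged genes. The 1.5-fold rule recovered 16 of 50 genes simulated at 1.5-fold and 50 of 50 at 2-fold, and called 5 of 13285 unchanged genes. Of simulated lists of 25 genes, 40 of 40 with a log2 shift of 0.2 and 0 of 40 without a shift stood apart. The simulation holds counting noise only.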

Results

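The transcriptome of human bone marrow stromal cells was measured after 21 days on SiN, A-Ti or M-Ti discs, with 1 pooled library per disc type. The estimated counts summed to 48766246 for SiN, 56454675 for A-Ti and 51646234 for M-Ti. Fibronectin (FN1), a matrix glycoprotein, took 8.97% of the counts in SiN, 8.44% in A-Ti and 9.03% in M-Ti. Mitochondrially encoded genes took 5.76%, 5.02% and 5.51%. The 3 libraries were close to each other: of 3461 genes with over 50 CPM, 99.5% lay within 1.5-fold between SiN and A-Ti, 99.9% between SiN and M-Ti and 99.6% between M-Ti and A-Ti. Each difference below is one between libraries, without a replicate check, and its interval covers counting error only.

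The SiN library differed from both titanium libraries in a way that followed the GC content of transcripts. Across genes, which are not independent replicates, the Spearman correlation of the log2 fold with GC content was 0.45 for SiN against A-Ti and 0.47 for SiN against M-Ti, but 0.03 for M-Ti against A-Ti. The median log2 fold of SiN against A-Ti ran from -0.12 in the decile of genes with the lowest GC content to 0.25 in the decile with the highest. For that reason, values with this trend taken out are given beside many of the gene groups.

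**Figure D1:**
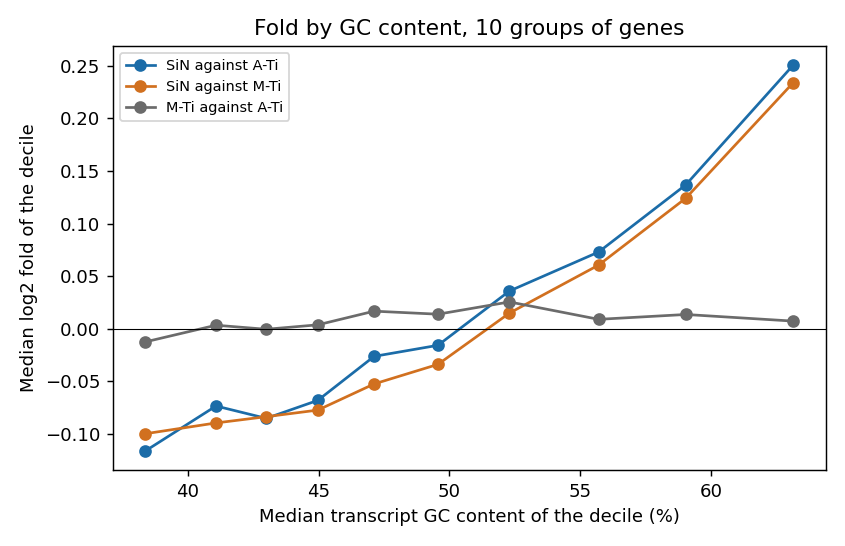
Median log2 fold of TMM-scaled counts (vertical axis) in 10 groups of genes ordered by transcript GC content (horizontal axis, percent), 1 line per comparison. Both SiN lines climb with GC content, to 0.25 against A-Ti and 0.23 against M-Ti in the highest decile, where M-Ti against A-Ti stays at 0.01.

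The main comparison set SiN against the titanium discs to ask how silicon nitride acts on bone-forming cells. The fixed lists that stood apart on the higher side against both titanium libraries, before and after the GC trend was taken out, were those of amino acid starvation and unfolded proteins, of NRF2 antioxidant genes, of mitochondrially encoded OXPHOS subunits and of nuclear-retained RNAs. Adipocyte markers, cholesterol synthesis and lysosome genes did so against both only before that correction. HSPA5, the main chaperone of the endoplasmic reticulum, lay at 1664 CPM in SiN against 1173 in A-Ti and 1333 in M-Ti. NQO1, a quinone reductase controlled by NRF2, lay at 55.0 CPM against 33.8 and 36.1. FASN, the fatty acid synthase, lay at 49.01 CPM against 31.3 and 33.2. All of these differences were below 2-fold. On the lower side, the mitochondrial ribosome stood apart against both titanium libraries before and after the GC trend was taken out. The lists of glycolysis, hypoxia response, YAP/TAZ target genes and contractile genes did so against both only after that correction. Contractile genes then lay at percentiles 0.71 against A-Ti and 0.03 against M-Ti. Of 40 lists with a percentile, 11 stood apart on the higher and 7 on the lower side in SiN against A-Ti. In SiN against M-Ti these counts were 11 and 2, and in M-Ti against A-Ti 8 and 10. With the GC trend taken out they were 9 and 15, 6 and 9, and 8 and 11. Standing apart was therefore common between any 2 of these libraries and not particular to SiN.

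Of the 13639 genes compared, 11 were at least 2-fold higher and 11 at least 2-fold lower in SiN than in both titanium libraries. None of these 22 reached 5 CPM, and the rule for named genes therefore took none of them. Chosen after their values were seen, the named protein-coding genes among them were TRAF2, AGAP5 and YJEFN3 on the higher side and ACTG2 and CPA3 on the lower side. TRAF2, an adaptor of tumour necrosis factor receptors, lay at 2.43 CPM in SiN against 1.16 in A-Ti and 1.11 in M-Ti, and ACTG2, a smooth muscle actin, at 0.69 CPM against 1.72 and 1.90. The other 17 were read-through genes, pseudogenes, a noncoding RNA or genes without a symbol. For scale, A-Ti had 11 genes higher and 20 lower than both other libraries by the same rule, and M-Ti had 10 higher and 33 lower; at 1.5-fold these counts were 58 and 94 for A-Ti, and 40 and 108 for M-Ti. At 1.5-fold, 90 genes were higher and 44 lower in SiN than in both titanium libraries, and 48 and 40 once the GC trend was taken out. With the threshold at 5 CPM, 9 genes were higher and 5 lower at 1.5-fold.

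Among genes with at least 5 CPM, 4 named protein-coding genes were at least 1.5-fold higher in SiN than in each titanium library, namely SLC52A2, NQO1, HSPA1A and, outside the rule for named genes and chosen after its values were seen, PITPNM1. SLC52A2, a riboflavin transporter (ENSG00000185803, chromosome 8, 144333957 to 144361286), had log2 folds of 0.95 (0.69 to 1.21) against A-Ti and 0.90 (0.63 to 1.17) against M-Ti. Its transcripts are GC-rich, at 64.5%, and the folds were 0.68 and 0.64 after the GC trend was taken out. NQO1 (ENSG00000181019, chromosome 16, 69706996 to 69726668) had log2 folds of 0.70 (0.62 to 0.79) and 0.61 (0.52 to 0.69), and of 0.73 and 0.65 after that correction. PITPNM1, a phosphatidylinositol transfer protein, lay at 12.2 CPM in SiN against 7.43 in A-Ti and 7.65 in M-Ti. On the lower side, GMNC was the 1 named protein-coding gene, at 4.17 CPM in SiN against 7.08 in A-Ti and 7.61 in M-Ti. HSPA1A lay at 142.8 CPM in SiN against 85.3 and 94.5, and its near-identical copy HSPA1B at 75.9 CPM against 48.5 and 51.5; the split of reads between both is uncertain. The pseudogenes SMG1P1 and RPL29P11 were lower in SiN by more than 1.5-fold against each, with values as uncertain.

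Oxidative phosphorylation is the first subject of the series title. The 13 mitochondrially encoded subunits were more abundant in SiN than in A-Ti, whereas the 77 nuclear-encoded subunits were not. The mitochondrially encoded list had a median log2 fold of 0.27 in SiN against A-Ti (interquartile range 0.21 to 0.31), 0.07 in SiN against M-Ti and 0.18 in M-Ti against A-Ti, at percentiles 100, 99.95 and 100 of random lists. With the GC trend taken out these medians were 0.32, 0.14 and 0.18. Against A-Ti, 12 of the 13 were higher in SiN and 1 was lower beyond counting error; against M-Ti these numbers were 11 and 2. MT-CO1, the most abundant, lay at 8860 CPM in SiN, 7786 in A-Ti and 8782 in M-Ti. MT-ND4 (mitochondrial genome, 10760 to 12137) lay at 7655, 6531 and 7383 CPM, and MT-ATP6 at 4195, 3389 and 3997 CPM. MT-ND6, the only subunit encoded on the light strand, lay at 24.5, 17.9 and 15.8 CPM. Set among random lists that were not matched on expression, the SiN against M-Ti median fell to percentile 89.1 and no longer stood apart.

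The 77 nuclear-encoded subunits had a median log2 fold of -0.04 in SiN against A-Ti (percentile 9.1), -0.02 in SiN against M-Ti (percentile 61.1) and -0.06 in M-Ti against A-Ti (percentile 0.0). By total counts the SiN against M-Ti median was 0.03. Against A-Ti, 12 were higher in SiN, 30 were lower and 35 did not differ beyond counting error; against M-Ti, 18 were higher, 22 lower and 37 did not differ. None was 2-fold apart. With the GC trend taken out, the SiN against A-Ti median lay at percentile 0.2, and with the GC and length trends taken out at 4.79, where it did not stand apart. NDUFB5 of complex I (ENSG00000136521, chromosome 3, 179604690 to 179627647) lay at 43.6 CPM in SiN against 61.2 in A-Ti and 58.2 in M-Ti. NDUFS8 of the same complex (ENSG00000110717, chromosome 11, 68030617 to 68036644) lay at 11.6 CPM against 7.99 and 8.40. These 2 transcripts differ in GC content, at 39.7% and 62.7%. The abundant subunits ATP5F1B, COX4I1, ATP5F1A and UQCRB had log2 folds between -0.08 and -0.01 against both titanium libraries. By complex, the medians of SiN against A-Ti were -0.04 for complex I, -0.06 for complex II, -0.03 for complex III, -0.14 for complex IV (percentile 0.7) and -0.07 for the ATP synthase (percentile 13.1, and 1.28 with the GC trend taken out).

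**Figure D2:**
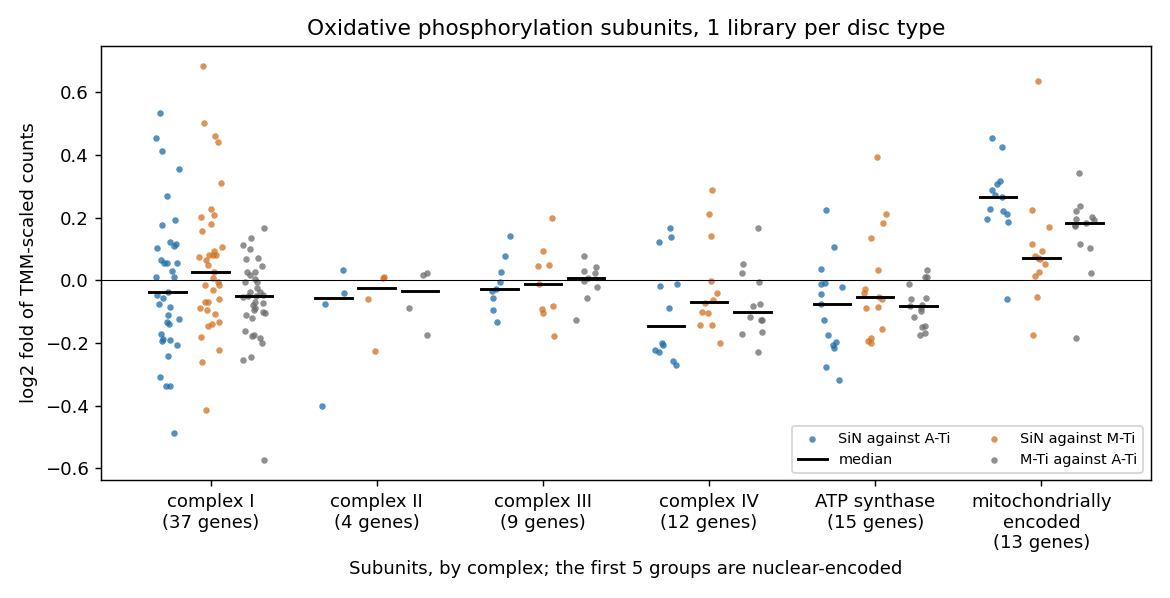
Log2 fold of TMM-scaled counts (vertical axis) of each OXPHOS subunit, grouped by complex (horizontal axis) and coloured by comparison, with a black bar at the median of the group. The mitochondrially encoded group sits at a median of 0.27 in SiN against A-Ti, and the nuclear-encoded groups sit between -0.14 and -0.03 in that comparison.

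Other mitochondrial lists, and glycolysis as a list outside the mitochondrion, stayed close to the level of matched genes or below it. The 77 proteins of the mitochondrial ribosome had medians of -0.07 against A-Ti and -0.07 against M-Ti, both at percentile 0.2. MRPS35 lay at 48.9 CPM in SiN, 59.0 in A-Ti and 57.1 in M-Ti. Enzymes of the citric acid cycle and pyruvate dehydrogenase did not stand apart, with medians of -0.02 and -0.04, the second of which turns positive by total counts, and with OGDH at 40.9, 33.7 and 37.2 CPM. Regulators of mitochondrial biogenesis had medians of -0.03 and -0.06, without standing apart, and TFAM, which packages mitochondrial DNA, lay at 32.0, 36.3 and 34.8 CPM. Fatty acid oxidation had medians of -0.05 and -0.05 (percentiles 19.6 and 17.0), and the first was -0.10 at percentile 1.25 with the GC trend taken out. Glycolysis had medians of 0.02 and -0.05 (percentiles 88.6 and 68.5), which lay at percentiles 0.7 and 0.0 with the GC trend taken out; LDHA lay at 3587 CPM in SiN, 4215 in A-Ti and 4096 in M-Ti.

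Neovascularization is the second subject of the series title. The 33 angiogenic secreted factors that passed the filter went both ways and did not stand apart as a list. Their median log2 fold was 0.00 in SiN against A-Ti (percentile 62.2), -0.04 in SiN against M-Ti (percentile 37.5; 0.01 by total counts) and 0.07 in M-Ti against A-Ti (percentile 96.8). Against A-Ti, 8 were higher in SiN, 13 lower and 12 did not differ beyond counting error; against M-Ti, 7 were higher and 13 lower. CXCL12, a chemokine that attracts endothelial progenitors (ENSG00000107562, chromosome 10, 44370165 to 44386493), lay at 65.8 CPM in SiN, 43.3 in A-Ti and 57.8 in M-Ti. TGFB1 lay at 96.3, 77.3 and 78.6 CPM. Connective tissue growth factor (CCN2) lay at 3341 CPM in SiN, 4451 in A-Ti and 3421 in M-Ti, and angiopoietin 1 (ANGPT1) at 406, 516 and 396 CPM. GREM1 lay at 962, 1109 and 1336 CPM. VEGFA, looked up after the data were examined, lay at 291 CPM in SiN, 285 in A-Ti and 308 in M-Ti. With a filter at 5 CPM the SiN against A-Ti median of the list lay at percentile 1.4, and with the GC trend taken out at percentile 1.9, both on the lower side.

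Angiogenesis inhibitors had medians of -0.04 against A-Ti and 0.00 against M-Ti (percentiles 37.2 and 77.9), with THBS1 at 5638 CPM in SiN, 6471 in A-Ti and 6308 in M-Ti. Of the endothelial markers, 3 passed the filter, too few for a percentile. Among these KDR, the main receptor of VEGFA, lay at 107.7 CPM in SiN, 123.9 in A-Ti and 106.8 in M-Ti. The hypoxia response list, which holds targets of hypoxia-inducible factors, had negative medians in SiN, of -0.17 against A-Ti (percentile 0.0) and -0.11 against M-Ti (percentile 4.8, and 0.0 with the GC trend taken out). In M-Ti against A-Ti the median was -0.06 (percentile 0.23), so that both other libraries lay below A-Ti. Of its 24 genes, 18 were lower in SiN than in A-Ti and 16 lower than in M-Ti beyond counting error. INSIG2 lay at 85.7 CPM in SiN against 112.2 and 107.4, and PDK1 at 57.6 against 70.0 and 67.5. DDIT4 went the other way, at 93.9 CPM against 79.2 and 69.5.

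Osteoblast differentiation markers did not stand apart in any comparison. The 13 that passed the filter, of 26 in the list, had medians of 0.01 in SiN against A-Ti (percentile 56.6), -0.03 in SiN against M-Ti (percentile 38.6) and 0.04 in M-Ti against A-Ti (percentile 70.3). Both medians that involve M-Ti change sign by total counts, and that of SiN against M-Ti was 0.03 with the GC trend taken out. Against A-Ti, 4 were higher in SiN and 3 lower beyond counting error; against M-Ti, 2 were higher and 3 lower. Alkaline phosphatase (ALPL; ENSG00000162551, chromosome 1, 21509397 to 21578410) lay at 15.8 CPM in SiN, 11.5 in A-Ti and 16.2 in M-Ti. Cadherin 11 (CDH11) lay at 433, 463 and 455 CPM, and osteoprotegerin (TNFRSF11B) at 54.6, 64.6 and 55.9 CPM. RUNX2, the master transcription factor of osteoblasts, looked up after the data were examined, lay at 49.6 CPM in SiN, 50 in A-Ti and 51.3 in M-Ti. Collagens and bone matrix genes had medians of 0.01 against each titanium library (percentiles 94.97 and 99.99), and of 0.00 and -0.03 (percentiles 70.6 and 74.0) with the GC trend taken out. COL6A1 lay at 888 CPM in SiN, 678 in A-Ti and 785 in M-Ti. LOX, which crosslinks collagen, lay at 2029, 2483 and 2319 CPM.

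The response to amino acid starvation and unfolded proteins was among the lists that were higher in SiN than in both titanium libraries. Its 30 genes had medians of 0.20 against A-Ti and 0.15 against M-Ti, both at percentile 100, and of 0.15 and 0.13, again at percentile 100, with the GC trend taken out. Beyond counting error, 22 were higher than in A-Ti and 4 lower, and 24 were higher than in M-Ti and 3 lower. HSPA5 (ENSG00000044574, chromosome 9, 125234853 to 125241382) had log2 folds of 0.50 (0.49 to 0.52) and 0.32 (0.31 to 0.33). The pseudokinase TRIB3, a target of ATF4, lay at 31.9 CPM in SiN against 18.2 in A-Ti and 23.3 in M-Ti. The secreted stress proteins MANF and CRELD2 lay at 75.9 against 54.5 and 58.2 CPM, and at 11.99 against 8.38 and 9.13 CPM.

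NRF2 antioxidant genes had medians of 0.10 against A-Ti (percentile 99.6) and 0.11 against M-Ti (percentile 100), with 11 of 22 higher and 1 lower than in A-Ti, and 14 higher and 3 lower than in M-Ti. With the GC trend taken out, the medians were 0.12 and 0.12. In M-Ti against A-Ti the NRF2 list had a median of 0.08 (percentile 97.16). With the GC trend taken out that median was 0.08 at percentile 97.97, where it stood apart as well. Besides NQO1, members with large differences were PGD, at 66.8 CPM in SiN against 48.8 in A-Ti and 57.2 in M-Ti, and the transketolase TKT, at 111.2 against 86.4 and 94.3 CPM. Adipocyte markers had medians of 0.18 against A-Ti (percentile 98.7) and 0.39 against M-Ti (percentile 100). The first lay at percentile 91.1 with the GC trend taken out, and the second at 100. In M-Ti against A-Ti the adipocyte markers had a median of -0.13 (percentile 0.84). Their members with the largest differences were lipid genes: besides FASN, these were SCD, which makes monounsaturated fatty acids, at 445 CPM in SiN against 322 and 387, the lipase inhibitor G0S2 at 7.66 against 4.88 and 5.73, and APOE at 37.2 against 35.1 and 22.4. The 6 nuclear-retained RNAs had medians of 0.26 and 0.22 (percentiles 99.4 and 99.5), with MALAT1 at 1193 CPM in SiN, 993 in A-Ti and 1105 in M-Ti and NEAT1 at 198.8, 166.0 and 179.9 CPM.

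Against A-Ti alone, 47 genes were at least 2-fold higher and 38 at least 2-fold lower in SiN. The genes with the highest folds among those with at least 5 CPM had different functions, and MMP1, CDC6 and NIBAN1 were among them. Interstitial collagenase (MMP1; ENSG00000196611, chromosome 11, 102789401 to 102798160) lay at 11.04 CPM in SiN against 4.76 in A-Ti, a 2.32-fold difference, and at 9.94 CPM in M-Ti. The replication licensing factor CDC6 lay at 5.83 against 2.88 CPM, and NIBAN1, a stress-responsive gene, at 72.9 against 38.0 CPM. Tissue plasminogen activator (PLAT) lay at 97.2 against 54.6 CPM. On the lower side, the noncoding RNA LINC02008 lay at 3.53 CPM in SiN against 7.73 in A-Ti, and the cell cycle regulator RGCC at 6.30 against 12.4 CPM. In M-Ti, LINC02008 lay at 3.58 and RGCC at 6.46 CPM, close to SiN. For both genes A-Ti was thus the library apart. At 1.5-fold, 331 genes were higher and 173 lower, and 207 and 170 with the GC trend taken out.

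Against M-Ti alone, 77 genes were at least 2-fold higher and 23 at least 2-fold lower in SiN. The higher side held interferon-stimulated genes, a list whose median was 0.85 in SiN against M-Ti (percentile 100) and 0.05 in SiN against A-Ti (percentile 73.1). Embryonic myosin heavy chain (MYH3) lay at 1.499 CPM in SiN against 5.79 in M-Ti. It lay at 1.18 CPM in A-Ti, so that for MYH3 the M-Ti library stood apart from both others. MFAP5, a microfibril protein, lay at 11.6 CPM in SiN against 20.1 in M-Ti. LSP1 lay at 12.9 CPM in SiN against 6.86 in M-Ti. VIM-AS1, antisense to the abundant vimentin gene, lay at 15.2 against 8.10 CPM, a value that is uncertain without knowledge of the strand setting. At 1.5-fold, 326 genes were higher and 128 lower, and 239 and 116 with the GC trend taken out.

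The 2 titanium libraries differed from each other as well: 45 genes were at least 2-fold higher and 67 at least 2-fold lower in M-Ti than in A-Ti, and 221 higher and 266 lower at 1.5-fold. At 1.5-fold the balance turned to 148 higher and 121 lower over named protein-coding genes, and to 57 and 52 with a filter at 5 CPM. This comparison gives the distance between 2 titanium libraries. Interferon-stimulated genes were lower in M-Ti and cell proliferation genes were lower in A-Ti. All 25 interferon-stimulated genes compared had lower values in M-Ti than in A-Ti, 23 of them beyond counting error, with a median of -0.59 (percentile 0.0). IFIT1 (ENSG00000185745, chromosome 10, 89392546 to 89406487) lay at 34.1 CPM in SiN, 36.7 in A-Ti and 16.0 in M-Ti. OAS1, a sensor of double-stranded RNA, lay at 5.86, 6.22 and 2.61 CPM, and its paralogs OAS2 and OAS3 at 17.0, 15.9 and 9.37 CPM and at 14.3, 13.9 and 7.69 CPM. Of the 28 cell proliferation genes, 22 were higher in M-Ti than in A-Ti beyond counting error and none lower, with a median of 0.48 (percentile 100). In SiN against A-Ti, 22 were again higher and none lower, with a median of 0.37. In SiN against M-Ti the list had a median of -0.10 (percentile 0.45), with 13 genes lower and 6 higher in SiN beyond counting error. The helicase subunits MCM2 and MCM5, which were highest in SiN, lay at 8.33, 5.46 and 6.23 CPM and at 5.004, 3.04 and 4.07 CPM in SiN, A-Ti and M-Ti.

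**Figure D3:**
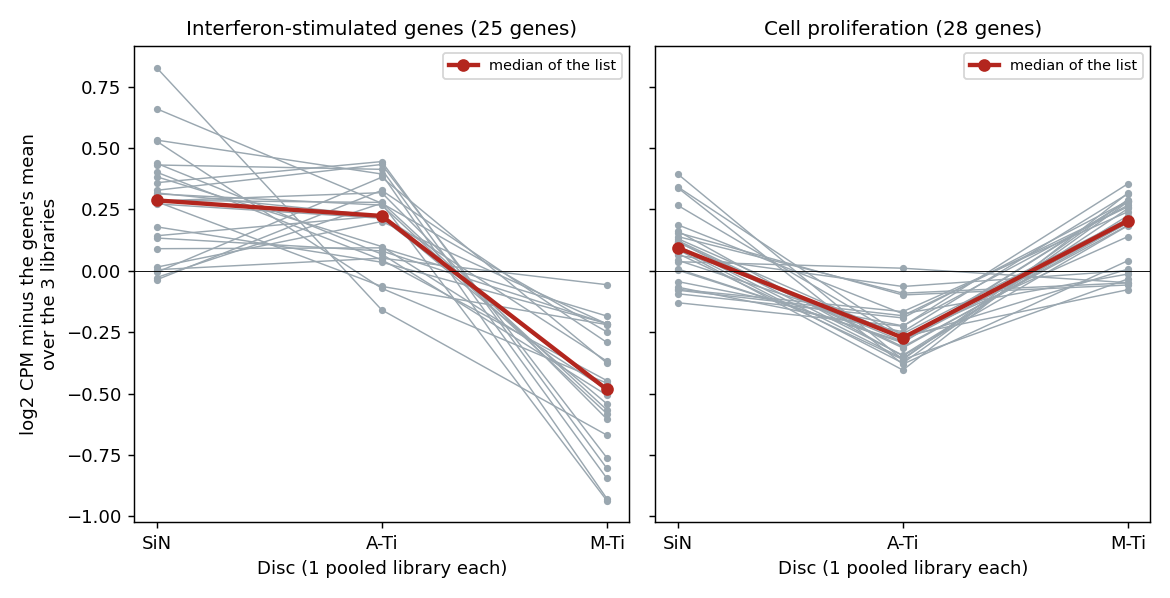
Log2 CPM of each gene minus its mean over the 3 libraries (vertical axis) by disc (horizontal axis), with 1 grey line per gene and the median of the list in red. The M-Ti library has the lowest median for the 25 interferon-stimulated genes and the A-Ti library the lowest for the 28 cell proliferation genes.

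Genes of cholesterol synthesis and of matrix proteolysis were also lower in A-Ti than in both other libraries. The 22 cholesterol genes had medians of 0.25 in M-Ti against A-Ti and 0.32 in SiN against A-Ti, both at percentile 100, with 15 and 18 genes higher beyond counting error. DHCR7, the last enzyme of the pathway, lay at 22.1 CPM in SiN, 15.7 in A-Ti and 18.3 in M-Ti. Matrix proteases and their inhibitors had medians of 0.19 in M-Ti against A-Ti and 0.20 in SiN against A-Ti, both at percentile 100, and did not stand apart in SiN against M-Ti, where the sign of the median depends on the scaling. With the GC trend taken out, the SiN against A-Ti median was 0.09 (percentile 98.2). CPA4, a carboxypeptidase, lay at 4.56 CPM in SiN, 2.28 in A-Ti and 5.93 in M-Ti. The axon guidance ligand SLIT2 and reelin (RELN) lay at 28.5, 17.6 and 33.3 CPM and at 13.6, 8.01 and 14.7 CPM. COL5A3 was highest in A-Ti, at 9.42, 15.5 and 7.45 CPM, and SERPINF1 was lowest in M-Ti, at 6.69, 7.20 and 3.74 CPM. BBS1, a ciliary gene, lay at 6.38, 5.85 and 2.89 CPM.

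**Figure D4:**
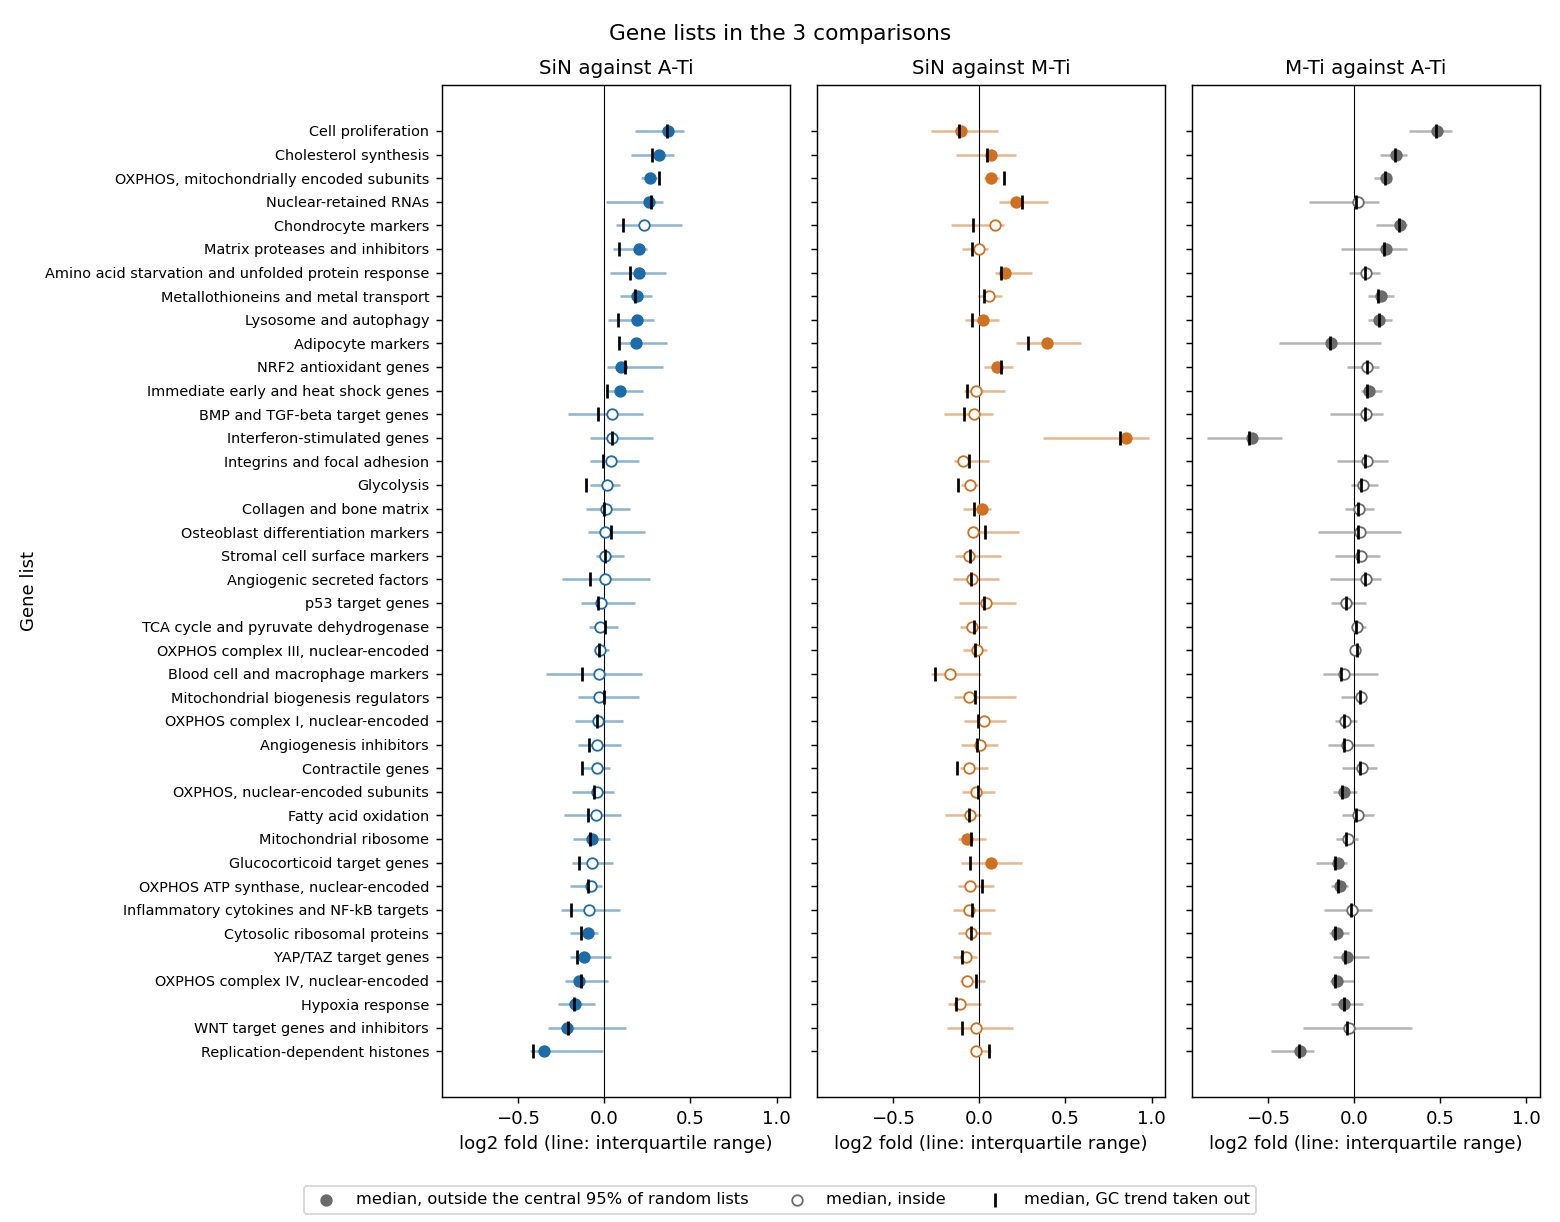
Median log2 fold (horizontal axis) of the gene lists with at least 5 compared genes (vertical axis), 1 panel per comparison; lines span the interquartile range, filled points lie outside the central 95% of random lists, and black ticks give the median with the GC trend taken out. Interferon-stimulated genes reach 0.85 in SiN against M-Ti, and cell proliferation reaches 0.48 in M-Ti against A-Ti.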

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

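The 1.5-fold threshold, the corrections for GC content and transcript length and the count over named protein-coding genes were chosen after seeing the data; the other alternatives were set before the data were examined. Scaling by total counts, by DESeq2 size factors or by TMM on nuclear-encoded genes, 5 added counts, thinning, and the fold without its counting interval left all 24 counts of genes within 1.5 times their main values. Of the results for the 4 main lists, 101 of 108 neither crossed into nor left the range that stands apart under the alternatives set beforehand, and 21 of 24 under the added ones; of those for the other lists, 911 of 963 and 170 of 216 did neither. These counts include medians close to 0 that changed sign. Of the folds of named genes, 3888 of 3969 stayed within their counting intervals under the former and 772 of 1134 under the latter. The 81 that moved under the former all moved under total counts. With 1 library per disc type, no library could be left out. Depths below that of the shallowest library were not tested. No alternative scaling moved the median of all genes by over 0.1.

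Counts of genes followed the filter, which by construction sets how many genes are compared; beyond that the cause was not tested. Without a filter, 343 genes were at least 2-fold higher and 271 lower in SiN against A-Ti, 392 and 231 in SiN against M-Ti, and 288 and 377 in M-Ti against A-Ti. Apart from both others were 85 higher and 66 lower in SiN, 82 and 101 in A-Ti, and 74 and 130 in M-Ti. With a filter at 5 CPM these counts were 2 and 2, 8 and 1, and 4 and 8, and apart from both others 0 and 0, 1 and 1, and 1 and 4. Over named protein-coding genes they were 22 and 13, 23 and 7, and 20 and 23, and apart from both others 3 and 2, 5 and 9, and 2 and 10.

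At 1.5-fold, in the same order, the counts without a filter were 675 and 454, 703 and 363, and 505 and 626, and apart from both others 183 and 109, 142 and 189, and 115 and 224. With a filter at 5 CPM they were 79 and 31, 53 and 14, and 57 and 52, and apart from both others 9 and 5, 11 and 19, and 4 and 26. Over named protein-coding genes they were 218 and 85 in SiN against A-Ti, 164 and 60 in SiN against M-Ti, and 148 and 121 in M-Ti against A-Ti, and apart from both others 42 and 17, 27 and 60, and 18 and 40. With the GC trend taken out, 207 genes were higher in SiN against A-Ti and 48 higher in SiN against both; with the GC and length trends taken out, these counts were 207 and 50.

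For the angiogenic secreted factors in M-Ti against A-Ti, the percentile of 96.8 passed the upper bound without a filter (99.6), with a filter at 5 CPM (99.0), after thinning (99.4) and among random lists not matched on expression (97.6). In SiN against A-Ti it moved from 62.2 to 1.42 with a filter at 5 CPM, to 1.88 with the GC trend taken out and to 0.96 with the GC and length trends taken out. For the nuclear-encoded OXPHOS subunits in SiN against A-Ti it moved from 9.13 to 1.64 with the mean of the list and to 0.20 with the GC trend taken out, but lay at 4.79, inside the central range, with the GC and length trends taken out. For the mitochondrially encoded subunits in SiN against M-Ti it moved from 99.95 to 89.1 among random lists not matched on expression. In SiN against M-Ti, the lysosome and autophagy list turned from a positive median at percentile 99.3 to a negative median at 19.7 with the GC trend taken out and at 19.6 with the GC and length trends taken out, and the glucocorticoid target genes from 99.9 to 18.25 and 13.96. The cause was not tested for these lists beyond the trend that the corrections remove.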

Other observations

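Several lists set A-Ti apart from the other libraries. The 7 replication-dependent histones compared had median log2 folds of -0.35 in SiN against A-Ti and -0.31 in M-Ti against A-Ti (percentiles 0.05 and 0.15), with 4 and 5 genes lower beyond counting error and none higher. H2AC6, a core histone, lay at 23.5 CPM in SiN, 33.0 in A-Ti and 23.9 in M-Ti. Polyadenylated RNA was sequenced, so histone transcripts without a poly(A) tail would be missed, and these values are no measure of cell proliferation. Lysosome and autophagy genes had medians of 0.19 in SiN against A-Ti and 0.15 in M-Ti against A-Ti, both at percentile 100, with 18 and 21 of 28 higher beyond counting error; the first was 0.08 (percentile 99.4) with the GC trend taken out. NPC1, which exports cholesterol from lysosomes, lay at 155.6 CPM in SiN, 94.7 in A-Ti and 169.0 in M-Ti, and the protease cathepsin D (CTSD) at 331.6, 249.6 and 294.4 CPM. Metallothioneins and metal transport had medians of 0.19 and 0.16 (both at percentile 99.9), with the metal-binding protein MT2A at 516, 363 and 427 CPM. The leptin receptor (LEPR), a marker of marrow stromal cells, lay at 211 CPM in SiN, 315 in A-Ti and 226 in M-Ti. The list of stromal cell surface markers did not stand apart in any comparison, with a median of 0.01 in SiN against A-Ti (percentile 78.9).

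WNT target genes and inhibitors had a median of -0.21 in SiN against A-Ti (percentile 0.2), with 4 of 13 lower and 3 higher beyond counting error; the WNT antagonist FRZB lay at 80.1 CPM in SiN, 113.8 in A-Ti and 69.9 in M-Ti, and WNT5A at 490, 614 and 557 CPM. YAP/TAZ target genes had a median of -0.12 in SiN against A-Ti (percentile 1.5), with 15 of 23 lower and 5 higher. Their median was -0.04 in M-Ti against A-Ti (percentile 2.0) and -0.07 in SiN against M-Ti (percentile 31.8, and 0.23 with the GC trend taken out). ANKRD1, a muscle ankyrin repeat protein, lay at 164 CPM in SiN, 235 in A-Ti and 181 in M-Ti, and IGFBP3 at 1019, 1318 and 1199 CPM. Of the 79 cytosolic ribosomal proteins, 55 were lower in SiN than in A-Ti and 59 lower in M-Ti than in A-Ti beyond counting error, with medians of -0.10 and -0.09. Their many pseudogenes share reads with them, so that values of single members are uncertain. Inflammatory cytokines and NF-kB targets did not stand apart in SiN against A-Ti, at percentile 6.6, but did with the GC trend taken out, where the median went from -0.09 to -0.19 (percentile 0.0), with CXCL8 at 37.7 CPM in SiN, 43.9 in A-Ti and 47.4 in M-Ti.

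Of the tests below, those on GC content for the count of genes and on nuclear pseudogenes for the mitochondrial transcripts were set before their results were seen, and all other tests in this part were chosen only after the result was seen.

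At 1.5-fold, 90 genes were higher and 44 lower in SiN than in both titanium libraries, a share of 67.2% higher (exact 95% binomial interval 58.5 to 75), where A-Ti had 58 higher and 94 lower and M-Ti 40 higher and 108 lower than both others. The share was 71.2% (57.9 to 82.2) among named protein-coding genes without read-through genes, so it does not rest on the kinds of genes left out there. Overlapping protein-coding genes and close paralogs stayed in that count, so split reads are not excluded. After thinning to one total the share was 69.2% (60.5 to 77.0). SiN is the shallowest library and was not thinned, and thinning keeps ratios on average, so depth is not decided. These intervals treat genes as independent, which they are not. A candidate explanation is a GC bias of the SiN library: within 3 gene families, the median of 6 Spearman correlations of fold with GC content was 0.639 (range 0.611 to 0.714) for SiN against titanium, and at most 0.06 for M-Ti against A-Ti. With the GC trend taken out, 48 genes were higher and 40 lower, a share of 54.5% (43.6 to 65.2). An effect of the disc on GC-rich transcripts stays open, because the SiN disc and the SiN library are the same sample here.

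Interferon-stimulated genes were lower in M-Ti than in both other libraries. The GC trend is too small to be the whole cause. Decile medians of SiN over M-Ti ran from -0.10 to 0.23, whereas the list had a median log2 fold of 0.85. With the trend taken out the list's median was 0.817, at percentile 100. After thinning it was 0.844, also at percentile 100, but thinning keeps ratios on average and cannot decide on depth. For blood cells in the SiN and A-Ti wells, the summed counts of 8 blood cell and macrophage markers had a log2 fold of SiN over M-Ti of -0.34 (-0.426 to -0.254). That sum rests on CD163, at 28.97 CPM in SiN, 23.8 in A-Ti and 39.1 in M-Ti. Without it the log2 fold was -0.05 (-0.225 to 0.125), which includes equal levels, so that blood cells stay open. CD74, an abundant transcript of antigen-presenting cells, lay at 0.344, 0.334 and 0.257 CPM, under the 1 CPM of the filter. The disc may set the level of the interferon-stimulated genes, but a difference between wells or libraries stays as open with 1 library per disc type.

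Mitochondrially encoded OXPHOS transcripts were higher in SiN than in A-Ti. GC content is argued against by the direction of the GC trend. These transcripts have a median GC content of 44.3%, and the gene decile at 45.0% had a median log2 fold of -0.07. Taking the trend out therefore raised their median, to 0.32 at percentile 100, and is no separate test. Nuclear pseudogenes held too few counts to account for the difference: 11 of them summed to 377 CPM in SiN and 296 in A-Ti. That is a loss of -1.3% of the gain of the 13 transcripts, which summed to 35183 CPM in A-Ti and 41493 in SiN. At this size the test on pseudogenes could not have come out in favour of the explanation. Mitochondrial genes of all kinds took 5.76% of the counts in SiN and 5.02% in A-Ti. Both mitochondrial rRNAs rose less than the transcripts. Their summed counts had a log2 fold of 0.079 (0.074 to 0.083), below the first quartile of the transcripts, 0.212. In M-Ti against A-Ti the log2 fold was 0.135 for the summed rRNAs and 0.192 for the summed transcripts. Polyadenylated RNA was sequenced, so the rRNAs may not gauge all mitochondrial RNA, and a higher share of it stays open. An effect of the disc on mitochondrial messenger RNA may be present, and a difference between wells or libraries stays as open.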
